A study of Myzus persicae with 4 samples.

How the data were processed

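The samples were 4 two-colour Agilent arrays of one design, each with RNA from heads of aphids on nicotine diet and on control diet, labelled with Alexa Fluor 555 and Alexa Fluor 647 by an indirect amino-allyl method per the labels' protocols. Each array had 15744 spots, of which 1116 were controls, and the other 14628 probes stood for 10489 contigs or other names. The arrays came from 1 slide and 1 scan, so neither could be tested as a batch.

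The deposited scanner files hold median spot and background intensity per channel, uncorrected, as read by Agilent Feature Extraction 10.1.1.1, per the file headers. They also hold processed intensity values, background-subtracted and dye-normalised by that software, and the log10 ratio of red over green made from them, per the file headers. The deposited value table holds a log2 ratio of red over green per spot, and the submitters' processing notes name limma without further steps. That scale and direction were found by setting each column against the same array's scanner ratio, with r of 0.960, 0.969, 0.959 and 0.967 and slopes of 0.799, 0.846, 0.819 and 0.843 on arrays 1 to 4. Against the normalisation used here, r was between 0.998 and 0.999. The slopes on it were between 0.997 and 1.006, and the differences had an SD between 0.026 and 0.040. The columns' medians were -0.03, -0.00, -0.03 and -0.01. The deposited ratios were thus centred near 0 much as the loess ratios used here, while the authors' exact steps stay unknown.

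Mean spot signals were not used here, so spot medians took their place. In limma 3.58.1 under R 4.3.3, the background was corrected by normexp with an offset of 50, and log2 ratios of red (Alexa Fluor 647) over green (Alexa Fluor 555) were normalised by loess within each array with control spots at weight 0. Ratios of arrays 1 and 3 were turned so that every ratio reads nicotine over control. Levels per channel were taken after a further Aquantile step between arrays. Probes with an outlier flag on any array (98) and probes well above background in a channel on fewer than 3 of the 4 arrays (2027) were left out, leaving 12503. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

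Titles and descriptions of the arrays differ. The title names array 3 as the technical replicate of replicate 1, while the description field gives array 4 as the technical replicate. The titles were followed, since they name the replicate that was repeated, and arrays 1 and 3 were averaged to 1 replicate. The test was limma's moderated test with a nicotine and a dye coefficient over 3 replicates, two-sided, with Benjamini-Hochberg adjustment at 0.05. It had 1 residual degree of freedom and 2.68 prior degrees of freedom. The labels do not say whether the replicates came from separate cultures, beyond calling them biological, so p-values measure the spread between these samples only.

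Contigs to be named were chosen by a rule fixed before the data were examined. With fewer than 5 probes past the threshold in a direction, the rule takes the 10 of smallest unadjusted p in that direction with the same direction on all 4 arrays, a probe per contig, given as values that do not pass. Because identifiers have no names, the first 2 in each direction are printed. Keyword gene lists and the receptor and detoxification genes that the rule also takes could not be tested, because the probes have no descriptions in the files used here.

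The model was tested on simulated data with the arrays' own spread and 50 probes changed at each of several sizes, all in the same simulated set. Of these it called 0 at a log2 change of 1, 13 at 2, 49 at 3 and 47 at 4. There were 11 false calls among the unchanged probes of the 12503 simulated. Alternatives covered which arrays share RNA, the dye term, background correction, normalisation, the deposited value table, the filter on dim probes, the moderation, a test against 1.2-fold, a threshold of 0.1 and leaving out each replicate or repeated array. Fits that left out a replicate had no dye term. A fit with the replicate as a random block returned no estimate of the correlation.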

Results

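Gene expression was measured in heads of the aphid Myzus persicae, a sap-feeding insect that colonises tobacco among many other plants. The aphids had fed for 24 h on a liquid diet of sucrose and amino acids that held either 250 µM nicotine or none. Nicotine is the main alkaloid of tobacco and activates the nicotinic acetylcholine receptors of the insect nervous system. RNA of both diets was hybridised together on each of 4 two-colour arrays, so that every array gave a ratio of nicotine to control diet for each probe. By their titles the arrays hold 3 biological replicates, with replicate 1 on arrays 1 and 3, replicate 2 on array 2 and replicate 3 on array 4. Nicotine RNA carried Alexa Fluor 555 on arrays 1 and 3 and Alexa Fluor 647 on arrays 2 and 4. Each array held 14628 probes other than controls, of which 12503 were tested, 12351 of them named for a contig (an assembled transcript sequence). The files do not pair these identifiers with gene names, and 0 of the 143 tested sequence accessions matched the reference table of names, so contigs are given by identifier and no functional gene group could be formed.

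The median spot intensity in the nicotine channel was 2720 on array 1, 2502 on array 2, 3470 on array 3 and 3022 on array 4. In the control channel it was 1200, 2112, 1714 and 2469 on the same arrays. Array 2 had the lowest share of probes well above background in the nicotine channel, 73.7%, against 88.0% on array 1, 87.1% on array 3 and 86.0% on array 4. In the control channel that share was 79.0%, 77.5%, 78.7% and 79.7% on arrays 1 to 4. No spot was saturated. The number of arrays limits the precision of every value given here.

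The comparison of nicotine with control diet asked which transcripts of the head respond to the alkaloid within 24 h. Of the contigs higher with nicotine, contig3265 had the smallest unadjusted p, with a log2 ratio of 2.64 ± 0.20 (SE, n = 3 replicates). It was followed by contig3321 with a log2 ratio of 1.84 ± 0.18 (SE, n = 3). In the other direction contig9835 had a log2 ratio of -3.45 ± 0.18 (SE, n = 3) and contig10031 one of -1.96 ± 0.19 (SE, n = 3). Because of the dye term, each coefficient weights replicate 1 as much as replicates 2 and 3 together and is not the mean of the replicates. The SEs rest on the difference between replicates 2 and 3, so they do not measure how far replicate 1 lies from the others. None of these contigs passed the test across all probes, where the adjusted p was 0.307 for each in limma.

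Contig3265 lay at 1.81 in replicate 1, 3.68 in replicate 2 and 3.26 in replicate 3. The second probe of contig3265 gave a coefficient of 2.22. Contig3321 lay at 1.69, 1.95 and 2.03 in replicates 1, 2 and 3, and its second probe gave 1.74. Both contigs were well above background in the nicotine channel of all 4 arrays and in the control channel of 3 of them, the exception being array 4, so that their ratios in replicate 3 are lower bounds. Contig9835 was at -5.06 in replicate 1, -1.76 in replicate 2 and -1.93 in replicate 3, so that its mean of -2.92 had a spread of 1.86 (SD, n = 3). Contig10031 lay at -2.87, -1.21 and -0.89 in replicates 1, 2 and 3. Fitted without the dye term, the coefficients with all 3 replicates were -2.92 for contig9835, -1.65 for contig10031 and 2.92 for contig3265. Leaving out replicate 1 as well made them -1.84, -1.05 and 3.47. Among the 10 contigs of smallest unadjusted p in each direction, coefficients ran from 1.38 to 2.64 with nicotine higher and from -3.45 to -1.53 with nicotine lower. A second probe was tested for 5 of the higher contigs and for 1 of the lower ones, and it had the direction of the first in 5 of 5 and in 1 of 1.

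**Figure D1:**
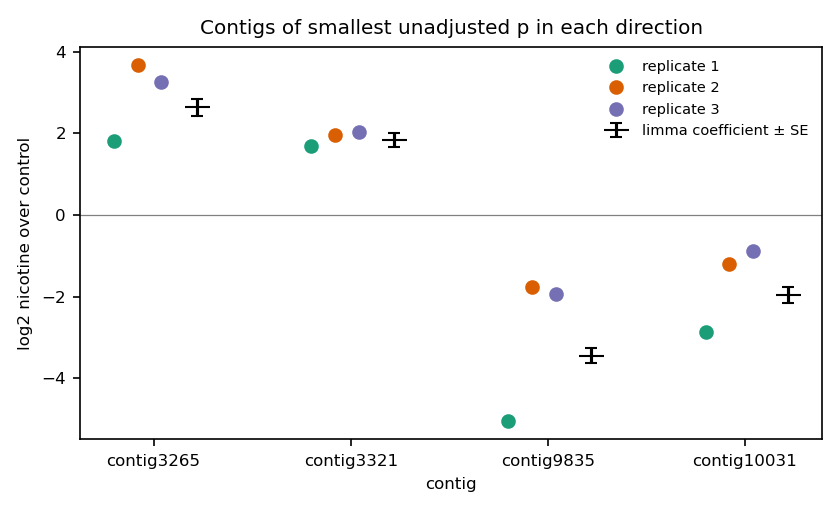
Log2 ratio of nicotine to control diet (vertical axis) for 4 contigs (horizontal axis), with a coloured point per replicate and a black bar for the limma coefficient ± SE. The coefficient weights replicate 1 as much as replicates 2 and 3 together, and the SE rests on the difference between replicates 2 and 3. Contig3265 and contig3321 lie above 0 and contig9835 and contig10031 below 0 in all 3 replicates, and contig9835 ranges from -5.06 to -1.76.

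Across the array, limma called 0 of 12503 probes different between diets at an adjusted p of 0.05, and the smallest adjusted p was 0.307. At an unadjusted p under 0.05 there were 1996 probes, 1022 with nicotine higher and 974 with nicotine lower, where 625 would be met by chance if no probe differed. Fitted without the dye term, that count was 2473 with all 3 replicates, 689 without replicate 1, 4085 without replicate 2 and 1039 without replicate 3. The array descriptions give array 4 as the technical replicate but name no array that it repeats. With array 4 taken as the repeat of array 1, 1752 probes passed with the dye term and 0 without it (3505 at an unadjusted p under 0.05). With the dye term contig3265, contig3321, contig9835 and contig10031 each had an adjusted p of 0.0424 in limma. That pairing counts arrays 1 and 3 as separate biological samples, although their ratios correlated at 0.985 across probes and differed by an SD of 0.13 (log2).

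A set of 20 probes from 15 contigs was at least 2-fold higher with nicotine in all 3 replicates, with a median coefficient of 1.59 and a range of 1.08 to 2.64. A further 21 probes from 18 contigs or other names were at least 2-fold lower in all 3 replicates, with a median of -1.59 and a range of -3.45 to -1.10. With the sign of replicate 1, 2 or 3 turned, the 2-fold sets held 0, 26 and 34 probes in place of 41. Probes with ratios of the same sign in all 3 replicates numbered 5769, or 46.1% of those tested, against 25% by chance for independent replicates. They comprised 2938 probes with nicotine higher and 2831 with nicotine lower. With the sign of replicate 1, 2 or 3 turned, 1434, 3503 and 1797 probes had a common sign. The 143 accession-named probes had 29 members higher and 38 lower in all 3 replicates, and 0 of them were 2-fold in all 3.

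The replicates differed in how well their probes matched. Across probes, which are not independent replicates, Pearson's r was 0.577 between replicates 1 and 3 (Spearman's rho 0.639) and 0.349 between replicates 1 and 2 (rho 0.293). Between replicates 2 and 3 it was -0.0016 (rho 0.171), and 57.6% of probes had the same sign in both. Contigs with both probes tested, 3795 in number, gave like values within each replicate, with r between the probes of a contig of 0.900, 0.962 and 0.895 in replicates 1, 2 and 3. At least 2-fold higher ratios were measured for 955 probes in replicate 1, 382 in replicate 2 and 894 in replicate 3, and at least 2-fold lower ratios for 844, 276 and 419.

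**Figure D2:**
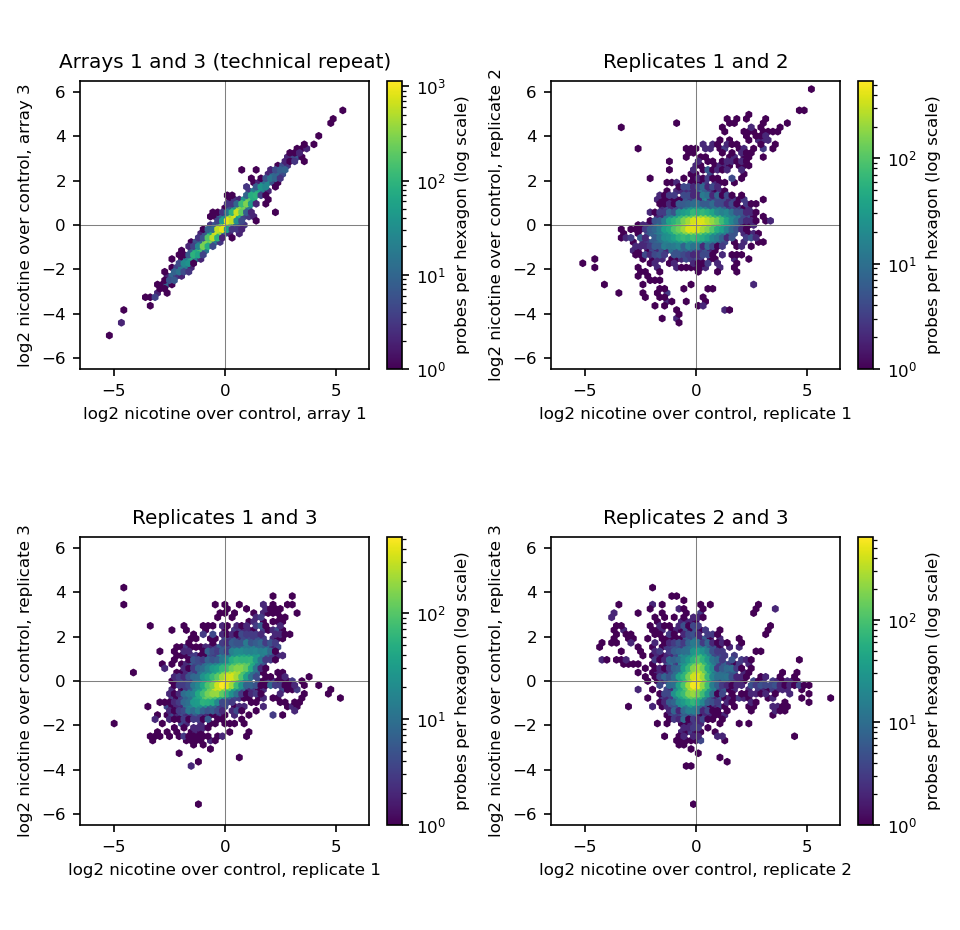
Log2 ratio of nicotine to control diet of each tested probe on pairs of arrays or replicates, with colour giving the number of probes per hexagon on a log scale. Points for arrays 1 and 3 follow the diagonal (r = 0.985), while replicates 2 and 3 form a cross with r = -0.0016, including probes with high ratios in replicate 2 and ratios near 0 in replicate 3.

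A group of 111 probes from 82 contigs or other names, picked out after their values were seen, was detected on arrays 1 to 3 and in neither channel of array 4, which holds replicate 3. Of these probes, 86 were at least 2-fold higher with nicotine in replicates 1 and 2 and 0 were at least 2-fold lower. Over all 12503 tested probes, 241 were at least 2-fold in one direction in both. Detection in either channel was enough, so probes dim with control diet could enter through the nicotine channel. The 1242 probes undetected only on array 2 also leaned upward, with 101 at least 2-fold higher and 9 lower in replicates 1 and 3. The median log2 ratio of the group was 1.97 in replicate 1 and 3.33 in replicate 2, but the control channel was well above background on all of arrays 1 to 3 for only 23 of the 111 probes, so that many of these ratios are lower bounds. Its median log2 level with nicotine was 9.71 in replicate 1, 11.28 in replicate 2 and 6.67 in replicate 3, and with control diet 8.09, 8.22 and 7.07. The upper quartile with control diet was 8.96, 9.09 and 7.85, but some members were bright there too. With control diet M_persicae130a lay at 12.94, 13.17 and 7.80 in replicates 1, 2 and 3, and M_persicae131a at 13.19, 13.16 and 8.08. In such members both diets were far lower in replicate 3, which is a difference between replicates. In replicate 3 the group was not well above background, so its ratio there has no meaning as a fold. Without the group, Pearson's r across probes was 0.262 between replicates 1 and 2, 0.618 between replicates 1 and 3 and 0.033 between replicates 2 and 3.

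**Figure D3:**
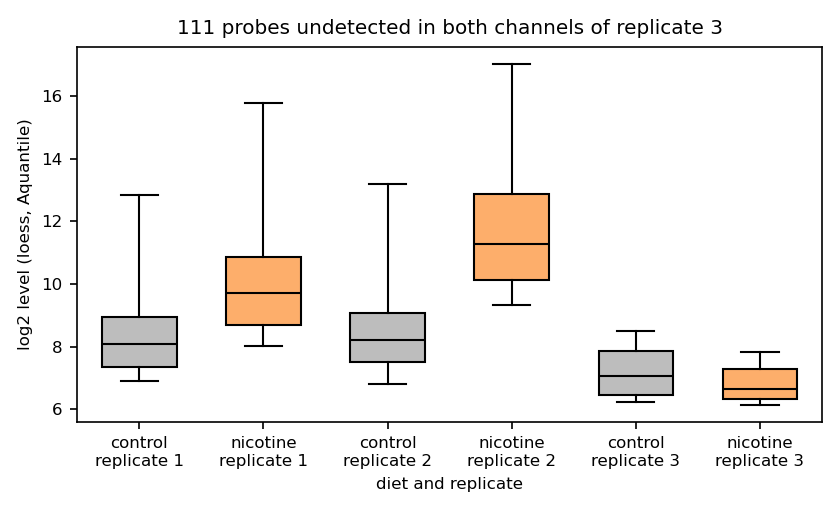
Log2 level (vertical axis) of 111 probes with control diet (grey) and nicotine (orange) in replicates 1 to 3 (horizontal axis). Boxes span the quartiles with the median as a line, and whiskers reach the 5th and 95th percentiles. The nicotine medians are 9.71 and 11.28 in replicates 1 and 2 and 6.67 in replicate 3.

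The dye coefficient of the same model passed for 0 probes in limma, with 256 probes at an unadjusted p under 0.05. That is fewer than the 625 that would be met by chance if no probe differed. The chance count of 625 is therefore only a rough guide for the nicotine coefficient too. Since nicotine carried Alexa Fluor 555 only in replicate 1, the dye term absorbs the difference between replicate 1 and the others. The standard errors rest on the difference between replicates 2 and 3, with 1 residual degree of freedom. That pair was the least alike, with an SD of differences across probes of 0.88 (log2). It was 0.76 for replicates 1 and 2 and 0.64 for replicates 1 and 3. The lack of calls therefore does not show that no transcript responded. On simulated data with the spread of these arrays, the model called 0 of 50 probes changed by 1 on the log2 scale, 13 of 50 changed by 2 and 49 of 50 changed by 3. All sizes were planted in the same simulated set, where many large changes ease the adjusted threshold. These shares therefore do not give the chance of calling a large change in the real data. There contig9835, at -3.45, had an adjusted p of 0.307 in limma.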

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

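The test of the spike-in controls was chosen only after their values were seen. Spike-in spots, which the comparison of diets does not use, gave a signal far above the negative controls and a ratio that differed between arrays. Over 10 spike-in sequences with 20 spots each, the mean log2 ratio of red over green was 0.16 on array 1, -0.07 on array 2, 0.15 on array 3 and -0.61 on array 4. Array 4 minus array 1 was -0.78 (SD between sequences 0.18), with 10 of 10 sequences lower on array 4. These ratios were taken after the loess step, which was fitted to the other probes, so they depend on where those probes were centred. Red stood for control diet on array 1 and for nicotine on array 4. The mean log2 level of the spike-ins was 14.83, 13.74, 15.28 and 14.91 on arrays 1 to 4, against 6.46 to 6.63 for the negative controls.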

How the results depend on the processing

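All alternatives were chosen before the data were examined. The count of 0 probes past the threshold in limma became 1752 with arrays 1 and 4 as the repeated pair and the dye term, and 3506 with the 4 arrays as independent samples. Both settings treat arrays 1 and 3 as separate samples, but so does the pairing of arrays 1 and 4 without the dye term, which gave 0. It stayed at 0 in the other 18 alternatives, each replicate left out included, although Aquantile scaling leaves ratios as they are and so tests nothing. The deposited values also differ little from the ratios used here. The count at an unadjusted p under 0.05, 1996 as reported, was 5189 and 6129 in those settings, 3505 with that pairing and no dye term, and 1146 in a test against 1.2-fold. It ranged from 689 to 4085 when a replicate or repeated array was left out, with 689 without replicate 1, 4085 without replicate 2 and 1039 without replicate 3. Fits that left out a replicate also had no dye term, and without that term all replicates together gave 2473. The 41 probes 2-fold in all replicates became 109 with arrays 1 and 4 paired and 76 with Agilent's processed signals. With a replicate or repeated array left out they ranged from 41 to 660, with 65, 241 and 660 without replicates 1, 3 and 2, where fewer replicates must pass by construction. Probes of a common sign, 5769 as reported, ranged from 5754 to 9272 with a replicate or repeated array left out, the highest without replicate 2, and from 4728 to 9272 over all alternatives. Beyond the effects of construction, the cause was not tested. Coefficients of contig3265, contig3321, contig9835 and contig10031 kept their sign in every alternative that held them, which re-pairing or leaving out arrays could not have changed since they were chosen for a common direction on all 4 arrays. Without replicate 1 and the dye term, contig9835 went from -3.45 to -1.84, contig10031 from -1.96 to -1.05 and contig3265 from 2.64 to 3.47. Dropping the dye term alone gave -2.92, -1.65 and 2.92. The correlation of replicates 2 and 3 stayed between -0.02 and 0.06. The random block could not be fitted, and the gene-list and slide alternatives were not run. Array 2, with 73.7% of probes well above background in the nicotine channel, limits dim probes in replicate 2.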

Other observations

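All tests in this part were chosen after the results were seen, except the sign flips of whole replicates.

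Of the 111 probes undetected in replicate 3, 86 were at least 2-fold higher with nicotine in both other replicates, and the ratios of all 111 in replicates 1 and 2 correlated at 0.698 across probes. Faulty single probes are argued against by the contigs that had a second probe, of which 29 of 34 (85.3%) had both undetected on array 4, and gene-specific dye bias by 100 of 111 probes (90.1%) with a common direction in replicates 1 and 2, which have opposite dyes. For lower sensitivity of array 4 the outcome moved with the limit used. Against the limit of the control channel, which is the higher, the group's median nicotine level in replicate 1 lay 0.63 above the 5th percentile of detected probes. That is within the bound of 1 log2 unit and so in favour. It lay 0.96 above the level from which 50% of probes are detected, which decided nothing. These limits were replaced, after they were seen, by those of the nicotine channel, which is the group's own. There the gaps were 1.12 and 1.71 (SD 0.22), the former within its spread of the bound and the latter beyond it, so the gaps do not settle the question. A median of 97.3% of probes with like nicotine levels in replicates 1 and 2 (lower quartile 90.9%) were also detected in that channel. This argues against lower sensitivity for most of the group. Its lower quartile of nicotine level in replicate 1 was 8.69, within 1 log2 unit of the channel's limit of 8, so for the dimmer probes lower sensitivity stays open. RNA of a single other source in uneven amounts was judged by the ratio of the SD between contigs to that between probes of a contig. It was 1.01 in replicate 2 and 2.14 in replicate 1 (resampled 0.567 to 1.69 and 1.49 to 3.59). That ratio decides nothing where most control channels are near background. A single source would also move the nicotine levels of all its probes alike between replicates. From replicate 1 to 2, the probes of contig448 went from 9.01 to 17.05 and from 8.77 to 16.91. Those of contig124 went from 10.92 to 15.10 and 10.75 to 15.11, and those of contig190 from 13.72 to 13.08 and 13.27 to 12.42. These levels argue against a single source for these contigs together. For the rest of the group it stays open, and a response to nicotine that differed between replicates was not tested.

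The labels disagree on whether array 3 or array 4 is the technical replicate, and only the title of array 3 names the replicate repeated, which is replicate 1. Deviations of average spot intensity of array 1 correlated at 0.901 with those of array 3 and at -0.586 with those of array 4, a difference of 1.49. Centring on the mean of the 4 arrays pushes the correlations of unlike arrays below 0 and so sets part of that size. Ratios, which were not centred in this way, also correlated more between arrays 1 and 3 (0.985) than between arrays 1 and 4 (0.576). Arrays 1 and 3 share a dye orientation that arrays 2 and 4 reverse, so dye effects may widen both gaps. The correlations alone therefore do not settle the question. Levels do argue against array 4 as the repeat of array 1. M_persicae130a lay at 16.32 with nicotine and 12.79 with control diet on array 1, against 6.67 and 7.80 on array 4. The second probe of its contig averaged 15.78 and 12.83 over arrays 1 and 3, against 6.69 and 7.77 on array 4. Arrays 2 and 4, which share a dye orientation, had intensity deviations that correlated at -0.0401, and whether arrays 1 and 3 share RNA or were only handled alike was not tested.

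Replicates 2 and 3 share a dye orientation, yet Pearson's r of their ratios over all probes was near 0, with a rho of 0.171. Their r lay below the mean of the other correlations by a difference of -0.465. Gene-specific dye bias would raise this r and so could not have caused the low value. That difference restates the pattern, and it does not show such bias to be absent. Without probes beyond 4-fold r was 0.143, with a difference of -0.117 from the lower of the other correlations, and among the brightest 25% of probes r was -0.0418, with a difference of -0.361. These values argue against a few large ratios and against low signal as the whole cause. Biological variation between replicates was not tested.

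The count of probes at an unadjusted p under 0.05, fitted without the dye term, was 2473. Of the 4 sign patterns of whole replicates, 1 gave as many, the real one, and the highest of the others gave 823. With 4 patterns no share under 0.05 can be reached.

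Array 2 left 1242 probes undetected that the other 3 arrays detected, of which 101 were at least 2-fold higher with nicotine and 9 at least 2-fold lower in replicates 1 and 3.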
